A study of Mus musculus with 4 samples.

How the data were processed

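Gene expression was measured by RNA sequencing in 4 libraries of mouse cells that the labels describe as uterine NK cells (CD3-negative, CD45-positive and NK1.1-positive, sorted by flow cytometry) at gestational day 11.5 from females mated with B6 males. The labels give 2 libraries of mice with Cre recombinase driven from the NK-cell gene Ncr1 (Ncr1Cre) and 2 libraries of mice without Cre, which served as the control. The rest of the genotype and the results that need it, among them those of 1 of the gene lists, are not reported here. Nothing in the labels says whether libraries of a genotype came from separate mice, so the p-values measure the spread between these libraries, which may be technical. Groups and replicate numbers were taken from the labels.

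The values are FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library) per gene, made by the authors with Cufflinks on the mouse build mm9 per the submitters' processing notes, which give no version. The aligner, the annotation and the treatment of multiply mapped reads are not given in the sources used here. Each file holds the same 21993 genes with an identifier, a symbol and 1 FPKM value. Of the identifiers, 21750 matched the reference gene table used here, and 20799 symbols were equal to the reference symbol. A spreadsheet had turned 27 symbols into dates, and these were replaced through their identifiers. The reference annotation is of a newer build than mm9, so no coordinates are given.

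FPKM values are not counts, and the files give no total of reads. The low values of genes with 1 annotated transcript were therefore searched for steps of whole fragments. The totals that made most low values whole, within a tolerance of 0.02 fragments, were 26060000 and 22590000 fragments in the Ncr1Cre libraries and 38540000 and 20930000 in the control libraries. Between 40.9% and 45.5% of the low values came out whole. The lengths come from another annotation, which may be why the others did not, but this was not tested. On simulated libraries with known totals the largest error was 0.309%. These totals are estimates and no count test was run. At them, 1 fragment on 1 kb of transcript was worth 0.0259 to 0.0478 FPKM, so values well below 1 rest on few fragments. Replicates were compared with Poisson noise on genes with at least 20 fragments: the median chi-square was 2.12 in Ncr1Cre and 1.94 in control against 0.455 from sampling alone. Errors in these totals and lengths and in the assignment of reads would raise it too, so it does not show whether the replicates are separate libraries, and they were counted as separate because the labels list them so. Some exact zeros and unstable values are failed estimates: Gapdh, used by every cell and chosen after its values were seen, was listed at 2.25 and 13.3 FPKM in one genotype and at 4.49 and 0 in the other. A gene at 0 is therefore given only as listed at 0.

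The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, on the 11762 genes with a mean of at least 1 FPKM over the 4 libraries. P-values are two-sided and adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, Ncr1Cre minus control, and understate the change of low genes. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so none was used for calls. A rule of size, fixed in addition, counted genes with means at least 1 apart on the log2 scale and no overlap of the genotypes. On simulated data for this comparison (5 runs on 11762 genes, with 200 changed) the test recovered 100% of changes of 2 and 97.6% of changes of 1 on the log2 scale, and 1.48% of its calls were false. The simulated noise was independent between genes and took its size from these replicates, and far fewer genes changed than were called in the data. These shares therefore do not carry over to the calls made here.

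Before the data were examined, 28 gene lists were fixed: NK-cell functions, pathways and markers of other cell types. The 23 lists with at least 5 tested members were tested with camera (preset correlation 0.01, adjusted over the lists), which compares a list with all other tested genes, and again with an estimated correlation and with fry. Calls within a list are given over all genes tested and adjusted over the list alone. The rule for named genes was fixed at the same time. It takes, among others, Ncr1, the sort-marker genes Ptprc, Klrb1c and Cd3e, the growth factors Ptn, Ogn and Spp1, the 10 largest rises and 10 largest falls among called genes with no overlap (immunoglobulin and T-cell receptor segments left out), and up to 4 members of each list with the smallest p, or 6 where more pass. Other genes are said to have been chosen after their values were seen.

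The alternatives were a pseudocount of 0.1, no filter and a mean of at least 5 FPKM, median rescaling, quantile normalization, the replicate number as a block, each library left out in turn, limma without a trend or with robust moderation, an adjusted p under 0.1, a size rule of 1.5-fold, and lists without the genes that the rule named one by one. A fit without genes over 4-fold apart between replicates and without mitochondrially encoded genes was added after seeing the data. Alternatives that need counts were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and depth was estimated with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.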

Results

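The transcriptomes of libraries labelled as sorted uterine NK cells at gd11.5 of gestation were compared between mice that carried Cre driven from Ncr1 (Ncr1Cre, n = 2 libraries) and control mice without Cre (n = 2). The comparison asks which genes differ between the libraries of these genotypes. The FPKM values summed to 460108 and 468192 in the Ncr1Cre libraries and to 384852 and 396770 in the control libraries, and the implied depth was 20930000 to 38540000 fragments. Values below are mean FPKM ± SD with n = 2 unless stated otherwise. Where both genotypes are given without a direction, the value of Ncr1Cre comes first.

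Ncr1 and the genes of the positive sort markers were low in both genotypes. Ncr1, which encodes the NK-cell receptor NKp46 and drives the Cre, was listed at 0 and 0.15 FPKM in the Ncr1Cre libraries and at 0.14 and 0.36 in the control libraries. Klrb1c, the gene of the sort marker NK1.1, stood at 0.80 ± 0.18 and 0.71 ± 0.37. Cd3e was listed at 0.080 and 0.13 in the Ncr1Cre libraries and at 0 in both control libraries, and low values of this gene go with the CD3-negative label. Ptprc, which encodes CD45, rose from 2.73 ± 0.23 to 4.77 ± 0.54 (log2 fold change 0.63, SE 0.12, adjusted p = 0.0103). Its adjusted p was 0.0520 without replicate 2 of the control. In the same libraries Col1a1, a fibroblast collagen chosen after its values were seen, stood at 4487 ± 39.4 and 8141 ± 308 FPKM, Sparc at 3039 ± 117 and 8179.5 ± 163, and Epcam, an epithelial adhesion gene, at 122 ± 0.36 and 28.6 ± 1.16. The highest gene in the Ncr1Cre libraries was Prap1, a uterine epithelial gene chosen after its value was seen, at 47852 ± 2097 against 9598 ± 97.0. It took 10.1% and 10.5% of summed FPKM there.

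**Figure D1:**
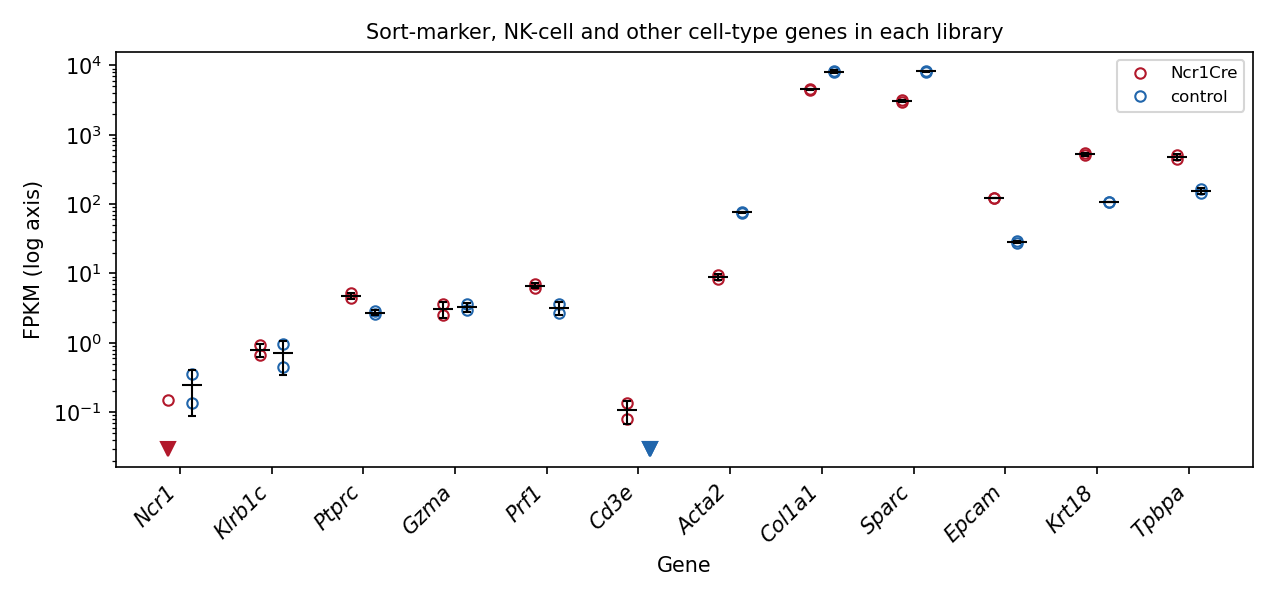
FPKM on a log axis of 12 genes in each library (open circles, red for Ncr1Cre and blue for control), with the mean and SD over n = 2 libraries where no library is listed at 0. Triangles at the bottom mark values listed at 0. Gzma, Prf1 and Col1a1 were chosen after their values were seen. Ncr1, Klrb1c and Cd3e lie below 1 FPKM in each library, and Col1a1 and Sparc lie at 2956 FPKM or more.

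Among growth-promoting factors, Ogn and Ptn were lower and Spp1 was higher in the Ncr1Cre libraries. Ogn, a small leucine-rich proteoglycan, fell 24.7-fold, from 166 ± 22.2 to 6.70 ± 0.89 FPKM (log2 fold change -4.44, SE 0.13, adjusted p = 0.000126). Ptn, which encodes the heparin-binding factor pleiotrophin, fell 4.46-fold, from 38.6 ± 0.035 to 8.66 ± 0.88 (-2.04, SE 0.092, adjusted p = 0.000223). Spp1, which encodes osteopontin, rose 9.48-fold, from 185 ± 11.3 to 1753 ± 83.5 (3.24, SE 0.075, adjusted p = 0.000126). These 3 genes were listed beforehand because studies of uterine NK cells named them, so they are not independent evidence if a study chose them on these libraries. Of the 20 tested growth factors, 6 rose and 7 fell, over all genes tested and adjusted over the list alone. Hbegf rose from 10.3 ± 1.14 to 54.2 ± 2.83, Csf1 from 164 ± 18.8 to 568 ± 23.1 and Igf2 from 4.16 ± 0.42 to 15.7 ± 0.72. Camera did not call a shift of the list in one direction against other genes (adjusted p = 0.555), a test in which opposite changes cancel. The median log2 fold change of the list was 0.07 while the direction of its test was down. Stromal, smooth-muscle and epithelial marker genes differed between the same libraries, as given further on.

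**Figure D2:**
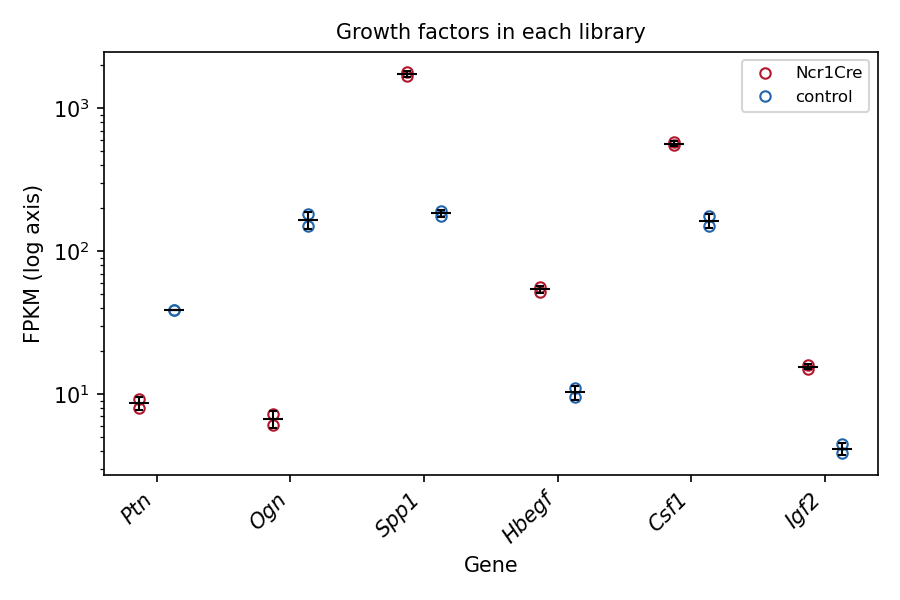
FPKM on a log axis of 6 growth factors in each library (red circles for Ncr1Cre, blue circles for control), with the mean and SD over n = 2 libraries. Ptn and Ogn lie lower and Spp1, Hbegf, Csf1 and Igf2 higher in both Ncr1Cre libraries than in both control libraries.

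Over all genes, 5709 of 11762 differed between the genotypes, with 3638 higher and 2071 lower in Ncr1Cre. The share of calls that were higher, 63.7%, depended on scaling. The median log2 fold change over tested genes was 0.11, and with that shift removed by median rescaling 2950 were higher and 2709 lower (52.1% higher), while quantile normalization gave 2615 higher and 3032 lower (46.3% higher). By the rule of size, 1154 genes were at least 2-fold higher and 317 at least 2-fold lower without overlap. These counts depended on scaling as well, with 976 higher and 484 lower after median rescaling and 882 and 562 after quantile normalization, and they were 1529 and 514 with a pseudocount of 0.1. Of the tested genes, 76.2% did not overlap, where chance gives 33.3% per gene for 2 against 2 exchangeable libraries. Genes of a library can move together, so this excess does not tell genotype from any other difference between the libraries. The largest rises were those of Gm20547, mt-Atp6, Hba-a2, Rpl10-ps3, Abcb1a, Lrg1, Hbb-y, Prl6a1, Spp1 and Lcn2. Among them Lrg1 rose from 36.1 ± 0.71 to 411 ± 0.045 FPKM, Lcn2, an iron-siderophore binding protein of epithelia and neutrophils, from 249 ± 11 to 2354 ± 212, and Prl6a1, a placental prolactin-family gene, from 2.65 ± 0.55 to 33.9 ± 2.49. Among the largest falls were those of Ogn, Gm8225, Myl12b, Actg2, Cnn1, Acta2, Myh11, Clec3b and Tagln, of which Clec3b fell from 168 ± 3.97 to 28.3 ± 2.70. Gm20547, which overlaps Cfb and C2, Abcb1a, which the reference marks as an overlapping locus, and Rpl10-ps3, Gm8225, Hba-a2, mt-Atp6 and Myl12b, which have near-identical copies or overlap another gene, are uncertain, and Myl12b stood at 59.1 and 14.4 FPKM in the 2 control libraries.

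Cytotoxic effector genes more often rose than fell in the Ncr1Cre libraries, in which Ptprc was 1.75-fold higher too. Of 17 tested, 10 rose and 2 fell over all genes tested, and 11 rose and 2 fell adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 0.0222, adjusted p = 0.451 with an estimated correlation). Gzmg rose from 26.4 ± 0.36 to 95.4 ± 4.71 FPKM, Gzmd from 24.2 ± 1.02 to 85.0 ± 5.52 and Ctsc, which encodes the protease that activates granzymes, from 24.4 ± 1.49 to 70.8 ± 4.58. Gzmd, Gzme, Gzmf and Gzmg are close copies, so their separate values are uncertain. Gzma, abundant in NK cells and chosen after its values were seen, stood at 3.11 ± 0.82 and 3.31 ± 0.49 and did not pass the test. Among other genes chosen in this way, Gzmb rose 1.81-fold and Prf1 2.07-fold, and Nkg7 (4.84 ± 0.29 and 4.15 ± 0.17) did not pass. These values cannot tell higher expression per NK cell from a larger share of such cells. Of 35 NK receptor genes only 9 reached the filter. Of these 5 rose and 0 fell over all genes tested (6 and 0 adjusted over the list alone, median 0.87, camera adjusted p = 0.0385, adjusted p = 0.388 with an estimated correlation), and the list's adjusted p was 0.0704 without replicate 1 of Ncr1Cre, 0.0511 with the replicate block and 0.433 without the filter. The 5 were Lilrb4, Gp49a, Tyrobp (5.79 ± 1.16 to 13 ± 0.77), Fcer1g (2.53 ± 0.078 to 5.50 ± 0.83) and Fcgr3, which myeloid cells express as well. Macrophage and dendritic cell genes rose in the same libraries, with 10 of 14 higher and 2 lower over all genes tested and adjusted over the list alone (median 0.67, camera adjusted p = 0.0242, adjusted p = 0.387 with an estimated correlation, and 0.564 on genes with a mean of at least 5 FPKM). Cd14 rose from 6.99 ± 0.13 to 35.5 ± 2.69 and Cd68 from 4.92 ± 0.12 to 23.4 ± 1.06, while Sirpa fell from 18.8 ± 1.53 to 6.0 ± 0.70.

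Tested members of the lists of NK-cell subsets and regulators moved in both directions. Many members stood below the filter and were not tested, as the lists held 25, 20, 27, 25 and 13 genes in the order given here. Among the untested were Eomes (0.87 ± 0.011 and 0.47 ± 0.084 FPKM) and Tbx21 (0.77 ± 0.21 and 0.57 ± 0.013), chosen after their values were seen. Which cells gave the RNA of the tested members was not tested. Of 14 tested markers of tissue-resident NK cells and ILC1, 8 rose and 4 fell by both adjustments (camera adjusted p = 0.354). Tmem176a rose from 44.6 ± 1.89 to 115 ± 0.93 and Itga1, an integrin of tissue-resident cells, from 2.29 ± 0.17 to 5.81 ± 0.63, while Itgb3 fell from 25.5 ± 2.04 to 14.5 ± 0.17. Of 10 conventional NK markers, 4 rose and 2 fell by both adjustments, and 2 and 2 under quantile normalization (camera adjusted p = 0.945), with Irf8 up from 5.96 ± 0.53 to 11.9 ± 0.49 and Ly6c2 down from 8.03 ± 1.14 to 3.79 ± 0.24. Of 17 lymphoid transcription factors, 4 rose and 6 fell by both adjustments (camera adjusted p = 0.233). Runx1 rose from 3.10 ± 0.84 to 13.2 ± 0.059 and Maf fell from 51.6 ± 4.92 to 26.6 ± 0.38. Of 11 cytokines and chemokines, 6 rose and 2 fell over all genes tested, and 7 and 2 adjusted over the list alone (camera adjusted p = 0.350). Cxcl16 rose from 10.6 ± 1.31 to 25.3 ± 0.56 and Cxcl10 fell from 247 ± 9.85 to 136 ± 8.90. Of 5 tested ILC2 and ILC3 genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.770), with Arg1 up from 2.45 ± 0.57 to 10.9 ± 2.62.

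Markers of other uterine and placental cells differed strongly. Smooth-muscle genes fell in 9 of 9 tested (by both adjustments), with a median log2 fold change of -2.52 (camera adjusted p = 6.2e-07, adjusted p = 0.312 with an estimated correlation). Actg2, a smooth-muscle actin, fell from 81.2 ± 0.50 to 5.99 ± 0.71 FPKM, Acta2 from 76.2 ± 0.78 to 8.87 ± 0.85 and Myh11, smooth-muscle myosin, from 25.9 ± 1.61 to 2.67 ± 0.72. Of 26 genes of decidual stroma and fibroblasts, 23 fell and 2 rose by both adjustments (median -0.89, camera adjusted p = 2.9e-10, adjusted p = 0.312 with an estimated correlation). Postn fell from 1663 ± 112 to 473 ± 31.0 and Pdgfra from 113 ± 0.82 to 39.7 ± 1.01, and Prl8a2, a decidual prolactin-family gene, rose from 3.73 ± 0.54 to 23.3 ± 1.96. Epithelial genes rose in 11 of 12 by both adjustments, with a median of 2.03 (camera adjusted p = 1.8e-06, adjusted p = 0.312 with an estimated correlation). Elf3 rose from 24.8 ± 0.61 to 157 ± 1.11 and Cldn4, a tight-junction gene, from 44.9 ± 4.63 to 225 ± 10.4. Of 14 trophoblast genes, 12 rose and 1 fell by both adjustments (median 1.5, camera adjusted p = 6.8e-05, adjusted p = 0.388 with an estimated correlation), among them Prl7a2, from 19.4 ± 1.27 to 105 ± 4.75, and the spongiotrophoblast gene Tpbpa, from 155 ± 17.0 to 485 ± 45.7. Krt8 and Krt18 of that list are also expressed in epithelium. Erythroid genes rose in 6 of 6 by both adjustments (median 3.01, camera adjusted p = 0.000668, adjusted p = 0.388 with an estimated correlation), including the embryonic globin Hbb-y, from 0.27 ± 0.13 to 12 ± 1.58. Of 10 endothelial genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.214), with Cdh5 up from 3.18 ± 0.12 to 13.6 ± 0.30.

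**Figure D3:**
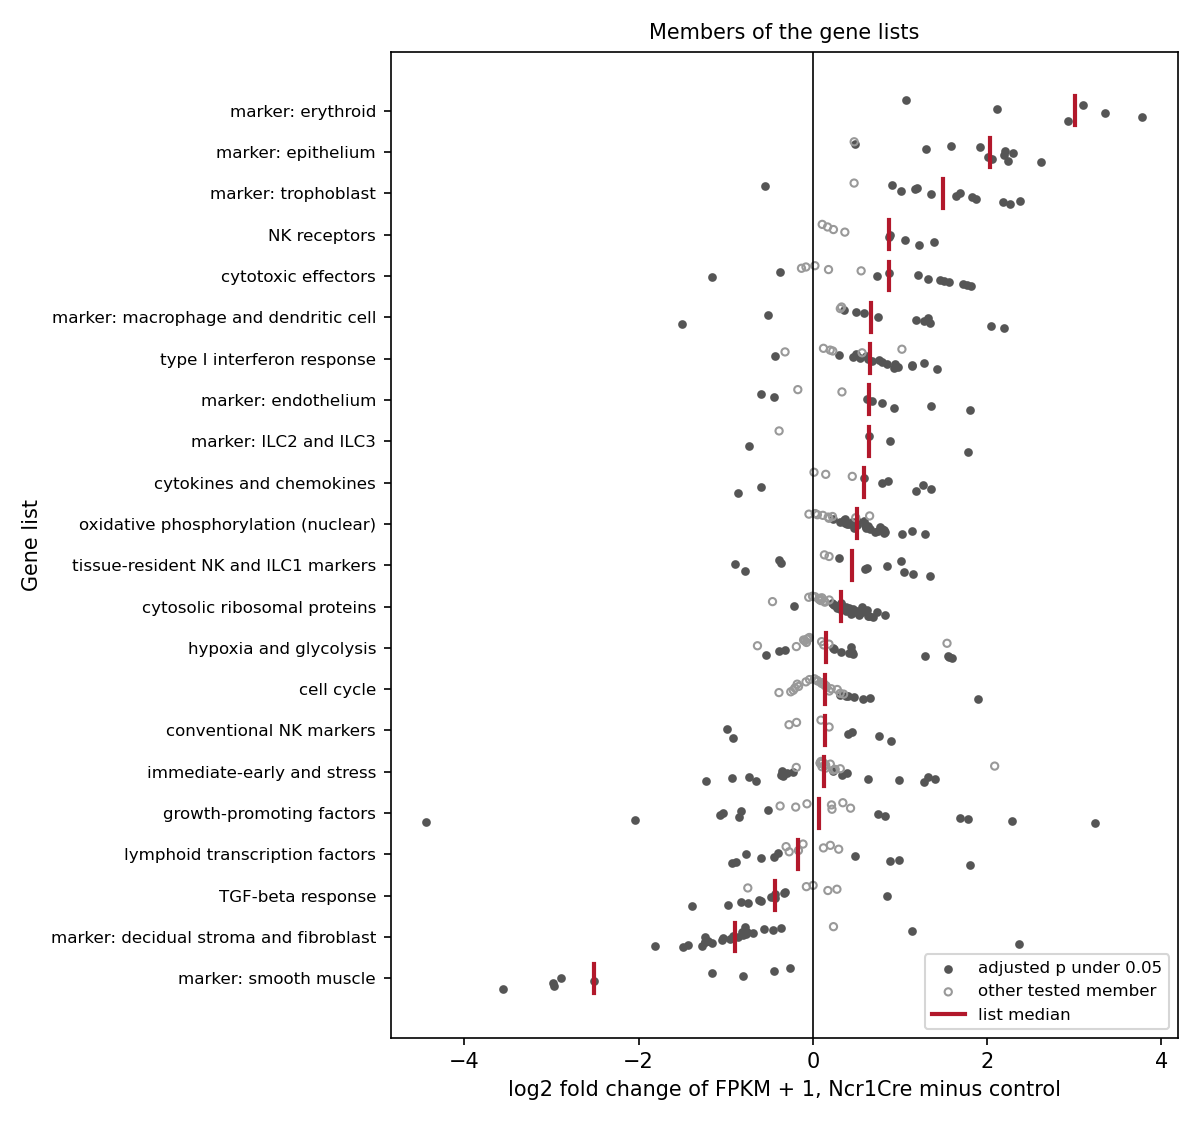
Log2 fold change of FPKM + 1 (Ncr1Cre minus control, horizontal axis) of each tested member of the gene lists described here that had at least 5 tested members. Filled points have an adjusted p under 0.05, open points do not, and red bars are list medians, which run from -2.52 for smooth muscle to 3.01 for erythroid genes.

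Lists with fewer than 5 tested members were not tested as lists. Of 4 neutrophil genes 2 rose and 1 fell, with S100a8 up from 0.78 ± 0.096 to 9.07 ± 1.09 FPKM. Of 3 B-cell genes 2 rose and 1 fell, and Ebf1, also expressed in stroma, fell from 7.72 ± 0.10 to 3.26 ± 0.72. Of 4 platelet genes 3 rose and 0 fell over all genes tested (3 and 1 adjusted over the list alone), with Ppbp up from 1.19 ± 0.19 to 7.71 ± 0.34. Of 2 mast cell and basophil genes, Hdc rose from 2.97 ± 0.18 to 22.9 ± 1.18 and Gata2 fell from 20.5 ± 0.55 to 13.8 ± 1.77, with an adjusted p of 0.0545 for Gata2 without replicate 1 of the control. Of 14 T-cell genes, 0 reached the filter.

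Nuclear genes of oxidative phosphorylation, ribosomal protein genes and type I interferon response genes were higher in the libraries in which epithelial, macrophage and dendritic cell genes and Ptprc were higher. Of 36 nuclear genes of oxidative phosphorylation, 27 rose and 0 fell over all genes tested (28 and 0 adjusted over the list alone, median 0.50, camera adjusted p = 9.2e-06, adjusted p = 0.329 with an estimated correlation), and 22 rose and 1 fell under quantile normalization. Ndufa6 rose from 46.3 ± 1.49 to 95.2 ± 4.70. Of 39 ribosomal protein genes, 26 rose and 1 fell by both adjustments (median 0.33, camera adjusted p = 0.00122, adjusted p = 0.561 with an estimated correlation), 16 and 1 after median rescaling and 16 and 4 after quantile normalization, and pseudogenes share their sequence. Rpl14 rose from 411 ± 2.33 to 646 ± 25.4. Of 24 type I interferon response genes, 17 rose and 1 fell over all genes tested and 18 and 1 adjusted over the list alone (median 0.66, camera adjusted p = 0.00159, adjusted p = 0.329 with an estimated correlation), but 14 rose and 2 fell after median rescaling and 11 and 2 after quantile normalization. Among them were Isg20, up from 26.1 ± 2.26 to 71.9 ± 3.03, and Bst2, from 139 ± 0.32 to 266 ± 7.67.

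TGF-beta response genes were lower, in the libraries in which stromal genes were lower. Of 17, 1 rose and 11 fell over all genes tested (3 and 12 adjusted over the list alone, median -0.44, camera adjusted p = 0.000668, adjusted p = 0.451 with an estimated correlation). The receptor gene Tgfbr2 fell from 430 ± 16.7 to 163 ± 8.19 and Ltbp3, which encodes a protein that binds latent TGF-beta, from 97.6 ± 10.7 to 49.0 ± 2.38. Of 28 cell-cycle genes, 7 rose and 0 fell over all genes tested and 3 and 0 adjusted over the list alone, but 3 rose and 3 fell after median rescaling and after quantile normalization (camera adjusted p = 0.555). Rrm2, a ribonucleotide reductase subunit, rose from 5.43 ± 0.26 to 22.9 ± 0.35. Of 26 hypoxia and glycolysis genes, 11 rose and 3 fell by both adjustments, and 8 and 4 after median rescaling and after quantile normalization (camera adjusted p = 0.555), with the glucose transporter Slc2a1 up from 20.5 ± 0.91 to 64.0 ± 0.42. Of 32 immediate-early and stress genes, 8 rose and 10 fell over all genes tested and 11 and 10 adjusted over the list alone, but 5 rose and 11 fell under quantile normalization (camera adjusted p = 0.770). The median of that list was 0.13 while the direction of its test was down. Tnfaip3 fell from 201 ± 5.58 to 85.6 ± 11 and Dnajb1 rose from 48.9 ± 1.76 to 121 ± 15.4.

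Camera called 13 of the 23 tested lists, and 0 with an estimated correlation, where the lowest adjusted p was 0.312. In that form camera rests on the few residual degrees of freedom of 4 libraries. Its lowest unadjusted p was 0.0299, for smooth-muscle genes, so hardly any list could pass after adjustment. Its lack of calls therefore does not decide whether a list changed. The preset form assumes a correlation of only 0.01 between members of a list. Where members move together more than that, its p-values are too small, so its 13 calls may be overstated. At 2 libraries per genotype the p-values rest on a spread shared across genes.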

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

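The fit without genes unstable between replicates and without mitochondrially encoded genes was chosen after seeing the data, and all other alternatives before. The count of 5709 changed genes lay between 4037 and 6759 under the alternatives that kept all libraries, with 4037 on the 7516 genes with a mean of at least 5 FPKM, 6759 at an adjusted p under 0.1 and 5776 in the added fit, which removed 50 genes. Leaving out 1 library gave 4154 to 4942 calls, with the lone library assumed to vary like the others, and the size rule then gave 1515 to 1584 genes. The correlation of replicate differences between the genotypes was 0.16 over genes, and the labels share only a number. The replicate block is therefore given only as an alternative, here and for the NK receptor genes above, and it gave 6004 calls and 12 called lists. At a 1.5-fold difference the size rule counted 3467 genes, since it is the looser bound. Of the 13 called lists, 0 held with camera and an estimated correlation, which has few degrees of freedom here and decides little. The fry test, which does not compare a list with other genes, called 20. Leaving out 1 library gave 12 or 13 called lists. The medians of 6 lists not called by camera changed sign relative to all genes, and the cause was not tested. Growth-promoting factors moved from -0.036 to 0.10 on genes with a mean of at least 5 FPKM and to 0.10 without the genes named one by one, such as Ptn, Ogn and Spp1, cytokines to -0.036 at that filter, lymphoid transcription factors to 0.068 without a filter, and immediate-early genes to -0.0044 with quantile normalization. Leaving out 1 library gave -0.012 to 0.087 for conventional NK markers, -0.0074 to 0.052 for hypoxia and glycolysis, and -0.084 to 0.086 for immediate-early genes. Of 153 called named genes, 11 lost their call in at least 1 alternative that tested them, 5 of them only with a library left out, and 0 reversed. A gene below the filter of an alternative was not tested there, and 119 of the 156 tested named genes reached a mean of at least 5 FPKM. The fits without a trend or with robust moderation and the adjusted p under 0.1 were not applied to named genes. Most of these genes were named for a small p or a large change, which favours calls that hold. Depth limits genes below about 1 FPKM, which include most NK receptor genes.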

Other observations

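The 4 lists in this paragraph, all tests of explanations after it, and Col1a1, Prf1, Gzma, Gzmb, Nkg7, mt-Nd4 and the genes named from these lists were chosen after the results were seen. The lists hold genes already seen to change, such as Lcn2 and mt-Atp6, so their counts and p-values are not independent evidence. Genes of uterine secretory epithelium rose in 13 of 13 tested (median log2 fold change 2.76, camera adjusted p = 5.7e-09, adjusted p = 0.0930 with an estimated correlation), among them Guca2b, from 1754 ± 25.4 to 12744.5 ± 20.1 FPKM, Pigr, from 36.7 ± 0.083 to 305 ± 0.054, and Ltf, from 134 ± 5.96 to 739 ± 40.4. Values are mean ± SD of n = 2 libraries. Of 11 mesothelial genes 8 fell and 1 rose (median -1.26, camera adjusted p = 2.1e-05, adjusted p = 0.0930 with an estimated correlation), with Upk3b down from 92.7 ± 4.53 to 25.8 ± 0.60. Of 7 yolk sac and fetal liver genes 5 rose and 1 fell (median 1.55, camera adjusted p = 0.0116, adjusted p = 0.220 with an estimated correlation), with Afp, the fetal counterpart of albumin, up from 1.43 ± 0.11 to 18.7 ± 1.16. Of 12 tested mitochondrially encoded genes 11 rose and 0 fell (median 1.41, camera adjusted p = 2.1e-05, adjusted p = 0.220 with an estimated correlation), and these genes held 4.66% and 5.13% of summed FPKM in the Ncr1Cre libraries against 1.86% and 1.99% in the control libraries.

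Many NK-cell genes were listed at low FPKM in the 4 libraries for cells sorted on CD45 and NK1.1. Ptprc, Tyrobp, Prf1, Gzma, Gzmb, Nkg7 and Il2rb stood at 2.53 to 13.6 FPKM in each library. Of 75 ribosomal protein and nuclear oxidative phosphorylation genes, which every cell uses, 2 (2.67%) were as low in any library. Failed FPKM estimates that bring genes in general as low as these NK-cell genes are therefore argued against. Smaller underestimates would pass, since the 75 genes are abundant. Their list medians were 538 to 674 FPKM for ribosomal protein genes and 44.5 to 69.5 for oxidative phosphorylation genes over the libraries. Gapdh, in another list, was as low in each library. The share of 2.67% also depends on the 7 genes chosen. Gzmd, Gzmf and Gzmg stood higher, with Gzmd at 85.0 ± 5.52 in Ncr1Cre and 24.2 ± 1.02 in control, while Ncr1 and Klrb1c stood lower. Failures confined to NK-cell genes stay open, as failed values can repeat between replicates, such as mt-Nd4 at 0.18 and 0.19 FPKM in the Ncr1Cre libraries and 0.084 in replicate 1 of the control against 239 in its replicate 2. RNA of other uterine cells making up most of each library is a candidate explanation: the median of the 26 stromal genes, all of which uterine tissue expresses, exceeded Ptprc by at least 19.9 times in each library, and Col1a1, 1 of them, stood at 4487 and 8141 FPKM. The sort should have removed such cells, and whether they, free RNA or another sample than the label names gave these values was not tested.

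Epithelial genes were higher and smooth-muscle genes lower in the Ncr1Cre libraries. Scaling is argued against, since a factor per library moves all genes the same way, and the medians of these lists had opposite signs. They lay 4.55 apart on the log2 scale. The SE of the difference of the list means was 0.47 over members, which come from the same 4 libraries and are not independent. A smaller share of stromal RNA alone would raise all other cell types, and the smooth-muscle median was -2.52. A different mix of uterine tissue carried into the libraries of each genotype may account for it, but it cannot be told apart from a response of the tissue to the genotype, which predicts the same with 2 libraries each and no label on dissection. That 92.5% of the 53 tested stromal, smooth-muscle, epithelial and erythroid genes changed in the direction of their list restates the calls of these lists and decides neither. Of 14 trophoblast genes 12 rose and 1 fell, and of 7 yolk sac and fetal liver genes 5 rose and 1 fell. The embryonic globin Hbb-y rose from 0.27 ± 0.13 to 12 ± 1.58 FPKM. Whether tissue of the placenta or embryo was part of the mix was not tested.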
